A study of Homo sapiens with 6 samples.

How the data were processed

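Total RNA of U2OS cells was labelled with biotin by the standard Affymetrix protocol and hybridised to 6 arrays, per the labels' protocols. The deposited values are log2 expression values per probe set, processed by the authors with the Bioconductor package oligo, per the submitters' processing notes. The version, the background correction, the summarisation and the genome build are not given in the sources used here. The log base was inferred from the values, which run from 0.687 to 14.0. Array medians from 5.10 to 5.14 showed that the arrays had been brought to a common scale, and the values were used as deposited with no further normalization. A normalization that equalises arrays also hides any change that moves all transcripts alike. Groups and replicate numbers were taken from the labels, and the 6 arrays made 3 groups of 2. The number of value columns left unused was 0.

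Probe sets were named from a table of the platform's annotation. Of 33297 probe sets, 19460 had exactly 1 gene symbol, 1754 had several and 12083 were unnamed here. For 19429 of the 19460, the symbol was looked up by Entrez ID in the RefSeq gene table of assembly GRCh38.p14. No gene was named from a probe set with several symbols. The 18417 genes included 769 with more than 1 probe set, and these probe sets were tested separately. A second probe set is given for some named genes only, so others may also differ between their probe sets. Since 0 probe sets were named for H3Y1 or H3Y2, the siRNA targets were not analysed here. Values of 975 probe sets equalled those of another probe set on all 6 arrays.

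Comparisons were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on all 6 arrays with 1 mean per group, so that the 3 groups shared 1 estimate of the spread (3 residual and 3.43 prior degrees of freedom). P-values were two-sided and adjusted by Benjamini-Hochberg over all probe sets within each of the 3 comparisons, and a probe set was called at an adjusted p under 0.05 with no fold minimum. Standard errors of log2 fold changes are those of the moderated fit. Gene lists were tested with camera at a preset correlation of 0.01 on 1 probe set per named gene, the one with the highest mean. Lists needed at least 5 measured genes, which left 23 lists, with Benjamini-Hochberg adjustment over them. Camera with an estimated correlation and fry were run beside it. Camera asks whether a list shifted relative to all other genes, and fry whether its genes moved on balance one way. With an estimated correlation 0 lists passed in each of the 3 comparisons, at a lowest adjusted p of 0.35 for H3.Y siRNA, 0.32 for the combined knockdown and 0.85 between them. Unlike the p at the preset correlation, this p rests on the 3 residual degrees of freedom, so few lists could pass. Oxidative phosphorylation after H3.Y siRNA had an estimated correlation of 0.0036, below the preset, yet its unadjusted camera p went from 0.011 to 0.070. The loss of calls is thus not a measure of gene correlation alone.

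Named genes were chosen by a rule fixed before the data were examined. It took the siRNA targets, then the 10 largest rises and the 10 largest falls among called probe sets with 1 symbol whose arrays did not overlap with those of luciferase (5 and 5 between the knockdowns), leaving out symbols of unnamed loci, open reading frames, small RNAs and olfactory receptors. It added up to 4 called members of each list with the smallest p, or up to 2 uncalled members as values where none passed, and up to 10 genes that the knockdowns called in opposite directions. Where more called members of a list or genes called in both comparisons are named, they were added after their values were seen. Gene lists covered histone genes, H3 chaperones, cell cycle phases, p53, interferon, NF-kB, unfolded protein, heat shock, cholesterol, hypoxia, growth factor, matrix, ribosomal, oxidative phosphorylation, apoptosis, microRNA and housekeeping genes, and epithelial, blood, and neuroectodermal and germ line markers for other cell types.

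The likeness of the comparisons with luciferase was set beside 100 simulations of unchanged groups sharing the 2 control arrays, and of groups sharing 1 control array, added after the values without each luciferase array were seen. The procedure was tested on simulated data, with 200 of 33297 probe sets changed in each of 10 data sets per comparison. For H3.Y siRNA, combined knockdown and the comparison between them, 13.1%, 15.0% and 13.7% of changes of 1 log2 unit were recovered, and 84.8%, 86.2% and 84.2% of changes of 2 log2 units. False calls made up 5.7%, 5.8% and 6.1% of calls. With so few changed probe sets, changes of 2-fold were thus mostly missed. The adjusted threshold is less strict where more probe sets change. In the data, called changes reached down to log2 0.72 in the combined knockdown and 0.61 between the knockdowns. Alternatives were a replicate block, only the 4 arrays compared, quantile normalization again, median centring, a filter on the dimmest 40% of probe sets, 1 probe set per named gene, eBayes with a trend and with robust variances, array weights, an adjusted p under 0.1, a minimum fold of 1.5, other list tests, and leaving out each array in turn.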

Results

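Transcript levels were measured in U2OS cells, an established human osteosarcoma line, after RNA interference against H3.X and H3.Y, which are primate-specific variants of histone H3. The cells were transfected 2 times with siRNA and harvested 4 days after transfection. The 6 arrays fell into 3 groups of 2 arrays each, namely luciferase siRNA as the control, H3.Y siRNA, and siRNA against both H3.X and H3.Y, called the combined knockdown below. The labels do not say whether that group received a pool of siRNAs or an siRNA that hits both genes. Each array carried 33297 probe sets with log2 values as deposited, of which 19460 carried exactly 1 gene symbol and stood for 18417 genes. Array medians lay between 5.10 and 5.14 log2 units. The labels call the arrays of a group biological replicates without saying how the cultures were separated, so the p-values measure the spread between these arrays. Arrays of the same group correlated across probe sets with r between 0.986 and 0.992, and arrays of different groups with r between 0.978 and 0.987. The SD of the difference between both arrays of a group was 0.333 for luciferase, 0.419 for H3.Y and 0.304 for the combined knockdown. With 2 arrays per group, the number of arrays limited the precision of every value.

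The knockdown itself could not be read on these arrays, since 0 probe sets were named for H3Y1 (the H3.Y gene) or H3Y2 (the H3.X gene) in the probe annotation used here. Among other H3 variant genes, H3-3B, which encodes H3.3, differed from luciferase by log2 -0.19 ± 0.15 (SE, n = 2 arrays per group) after H3.Y siRNA and by 0.02 ± 0.15 in the combined knockdown. H3-4 differed by 0.15 ± 0.23 and -0.10 ± 0.23, and H3-5 by -0.10 ± 0.15 and -0.13 ± 0.15. All 6 of these differences lay within the spread between replicates, with adjusted p between 0.65 and 0.97 (limma). These were the 3 measured genes of a list of 6, too few for a list test. The H3-5 probe set lay at 9.84 to 10.15 log2 units over the arrays, near that of H3-3B at 9.94 to 10.33. Whether it also reads H3-3B transcripts was not tested, so these may not be separate readings.

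H3.Y siRNA was compared with luciferase siRNA to ask which transcripts respond to loss of H3.Y. The largest rise among genes that the naming rule covered was that of ZP4, a zona pellucida glycoprotein. It was 25.7-fold higher after H3.Y siRNA (log2 4.68 ± 0.45 SE, n = 2 per group). Its difference was log2 3.98 without H3.Y replicate 1, where it was not called, and 5.39 without replicate 2. The chemokine CCL3 rose 13.3-fold (log2 3.73 ± 0.24) on a probe set that its near-identical gene copies may share, and MMP1, the interstitial collagenase, rose 8.59-fold (3.10 ± 0.25). The largest fall among probe sets with 1 gene symbol was that of RPN1, a subunit of the oligosaccharyltransferase that glycosylates proteins in the endoplasmic reticulum, at 4.26-fold lower (log2 -2.09 ± 0.12). Genes of DNA replication, mitosis and replication-dependent histones were called lower as lists by camera, by means of log2 -0.45 to -0.56, while H3C1 was the 1 member called over all genes. With an estimated correlation these lists had adjusted p between 0.35 and 0.43.

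In all, 93 of the 33297 probe sets passed an adjusted p of 0.05 in limma, 28 higher and 65 lower after H3.Y siRNA, and 4618 had an unadjusted p under 0.05. The called probe sets named 19 genes that rose and 52 that fell. Their median change was 2.88-fold, and all 93 changed at least 2-fold. ZP4, HCAR3, SPINK1 and PNLIPRP3 lay near the floor of the arrays in luciferase cells, at 3.57, 3.02, 3.17 and 3.92 log2 units, and NUCKS1 after H3.Y siRNA, at 3.75, so their folds depend on that floor. Other large rises were PNLIPRP3 (log2 3.51 ± 0.35), the trypsin inhibitor SPINK1 (2.80 ± 0.25), the protein kinase A inhibitor PKIA (2.73 ± 0.24), the hydroxycarboxylic acid receptor HCAR3 (2.30 ± 0.15), the long noncoding RNA PAX8-AS1 (2.22 ± 0.23), LRFN5 (2.08 ± 0.25) and the ubiquitin ligase subunit FBXO32 (2.01 ± 0.24), with adjusted p between 0.015 and 0.043. Other large falls were the mitochondrial carrier SLC25A24 (-1.88 ± 0.22), the transcription factor NFIB (-1.81 ± 0.14), the kinase UHMK1 (-1.79 ± 0.14), NUCKS1 (-1.78 ± 0.19), the COP9 signalosome subunit COPS2 (-1.76 ± 0.14), LYSMD3 (-1.74 ± 0.20) and the kinetochore protein NSL1 (-1.70 ± 0.15). MAGT1, another oligosaccharyltransferase subunit, fell by 1.97 ± 0.16 on the log2 scale on 1 probe set, while its second probe set gave 0.03. SMAD2, a signal transducer of the TGF-beta pathway, fell by 1.70 ± 0.17 on 1 probe set and gave 0.07 on the other.

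Among the gene lists fixed before the data were examined, camera called 9 of 23 after H3.Y siRNA, 8 lower and 1 higher. List means below carry the SD over the 2 knockdown arrays, which leaves out the spread of the luciferase arrays. The G1/S and DNA replication list averaged log2 -0.56 ± 0.17 below the luciferase arrays (SD over the 2 arrays, 41 genes measured). Of these genes, 40 were lower and 1 was higher, 0 passed over all genes tested and 26 fell when adjusted over the list alone (camera adjusted p = 3.6e-16, adjusted p = 0.35 with an estimated correlation). Its lowest unadjusted p belonged to CDC6, the replication licensing factor (log2 -0.88 ± 0.14, adjusted p = 0.081), and USP1 (-1.09 ± 0.19, adjusted p = 0.093). The G2/M and mitosis list averaged -0.47 ± 0.05 over 55 genes, of which 52 were lower. In that list 0 genes passed over all genes tested, and 25 fell and 1 rose when adjusted over the list alone (camera adjusted p = 1.1e-15, adjusted p = 0.35 with an estimated correlation). Examples were ANP32E (-1.64 ± 0.22) and the CDK subunit CKS1B (-1.24 ± 0.19), with adjusted p of 0.061 and 0.072 over all genes. Replication-dependent H1, H2A, H2B and H4 genes averaged -0.49 ± 0.23 over 43 genes, with 0 called over all genes, and 21 fallen and 1 risen when adjusted over the list alone (camera adjusted p = 2.9e-09, adjusted p = 0.43 with an estimated correlation). H2AC4 gave -1.04 ± 0.22 and H2BC4 -0.91 ± 0.19, and neither passed over all genes. Replication-dependent H3 genes averaged -0.45 ± 0.05 over 8 genes (camera adjusted p = 0.011, adjusted p = 0.35 with an estimated correlation). In that list H3C1 fell by 1.46 ± 0.18 on the log2 scale, close to the threshold at an adjusted p of 0.04998, and 2 genes fell when adjusted over the list alone. Histone genes of a class are near-identical copies, so a probe set of one may also read others.

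Genes of cholesterol synthesis and uptake averaged -0.32 ± 0.14 over 19 genes, 10 of which fell when adjusted over the list alone and 0 over all genes, with ACAT2 at -1.01 ± 0.15 and EBP at -0.64 ± 0.13 (camera adjusted p = 0.0012, adjusted p = 0.43 with an estimated correlation). Targets of p53 averaged 0.23 ± 0.08 over 30 genes, where the luciferase arrays had an SD of 0.13 (camera adjusted p = 0.0043, adjusted p = 0.49 with an estimated correlation). In that list 0 genes were called singly on either adjustment, with GADD45A at 0.82 ± 0.20 and CCNG1 at 0.72 ± 0.19. A further 3 lists had a camera adjusted p of 0.028, all lower. They were the CDK inhibitors and G1 regulators (mean -0.17, 10 fallen and 1 risen over the list alone), interferon-stimulated genes (mean -0.18, 0 called) and oxidative phosphorylation (mean -0.16, 0 called), and their adjusted p with an estimated correlation were 0.35, 0.69 and 0.35. E2F5 of the G1 regulators gave log2 2.29 ± 0.30, against SKP2 at -0.90 ± 0.14, neither past the threshold over all genes. COL6A3 fell by 1.41 ± 0.15 in the extracellular matrix list, which as a whole had a mean of 0.04 (camera adjusted p = 0.86). Fry called 2 of the 23 lists, the replication-dependent H3 genes (adjusted p = 0.019) and the G1 regulators (0.012). The 14 lists that camera did not call had adjusted p between 0.076 and 0.92, among them NF-kB and inflammatory genes (mean 0.31), hypoxia and glycolysis (-0.15), H3 chaperones (-0.09), growth factor immediate early genes (-0.17), unfolded protein response (-0.03), heat shock (-0.02), ribosomal protein (0.00), apoptosis (0.06), microRNA pathway (0.02) and housekeeping genes (-0.12). Markers of other cell types were not called either, with means of -0.15 for epithelial, 0.16 for blood and -0.03 for neuroectodermal and germ line markers. Mean and camera direction had the same sign in every list here, fry gave the extracellular matrix list a direction down, and the median differed from the mean in sign for the microRNA pathway and for neuroectodermal and germ line markers (median 0.05).

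The number of calls after H3.Y siRNA changed with the arrays in the fit. Leaving out either luciferase array, or either combined knockdown array, which is not part of this difference, gave 0 calls in limma with 1 residual degree of freedom fewer (2899 to 3736 probe sets at an unadjusted p under 0.05), leaving out H3.Y replicate 1 left 4 and replicate 2 gave 629, and a fit of only the 4 arrays compared called 0 (3709 at an unadjusted p under 0.05). Without luciferase replicate 2, camera called 4 lists instead of 9, keeping G1/S, G2/M, the replication-dependent H1, H2A, H2B and H4 genes and the cholesterol list. The cholesterol and G1 regulator lists were lost without H3.Y replicate 2, and the interferon-stimulated and oxidative phosphorylation lists without H3.Y replicate 1.

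**Figure D1:**
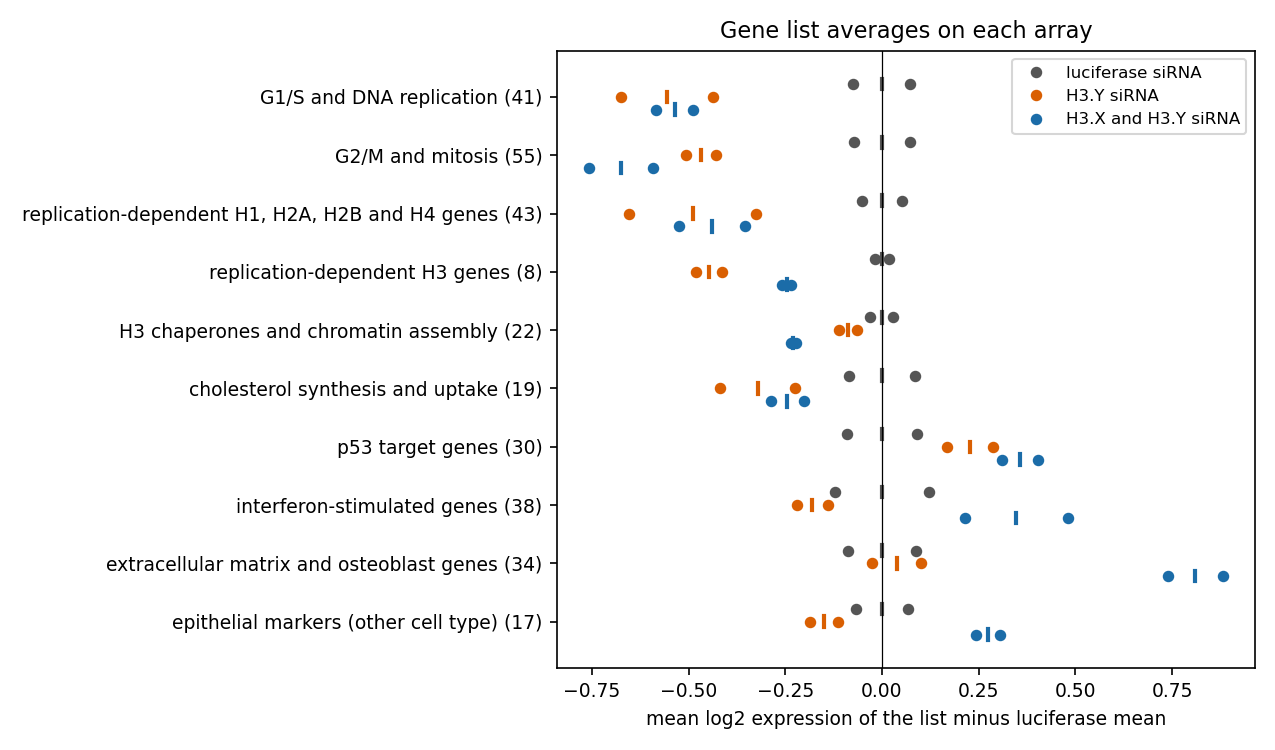
Mean log2 expression of each gene list on each array, relative to the mean of the luciferase arrays, with the number of measured genes in parentheses; points are arrays, coloured by group, and short vertical lines are group means (n = 2). The G2/M list lies at -0.51 and -0.43 on the H3.Y arrays and at -0.76 and -0.59 on the combined knockdown arrays, and the extracellular matrix list at 0.88 and 0.74 on the combined knockdown arrays.

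The combined knockdown was compared with luciferase siRNA to ask which transcripts respond when both variants are targeted. Lumican (LUM), a proteoglycan of the extracellular matrix, rose 19.3-fold (log2 4.27 ± 0.20 SE, n = 2 per group) from 2.17 ± 0.31 log2 units (SD) in luciferase cells, near the floor of the arrays, and the engulfment receptor MEGF10 rose 14.2-fold (3.83 ± 0.20). The extracellular matrix list was called higher by camera, with fibronectin (FN1) at log2 2.37 ± 0.29, thrombospondin 1 (THBS1) at 2.57 ± 0.27 and type I collagen (COL1A1) at 1.58 ± 0.17. The G2/M and mitosis list was called lower, and with an estimated correlation the adjusted p was 0.32 for each. Outside that list, the spindle checkpoint protein MAD2L1 was 4.56-fold lower (log2 -2.19 ± 0.16) and the kinetochore protein CENPH lower by log2 -2.32 ± 0.27. Among genes that the naming rule covered, the largest fall was that of SRP9, a protein of the signal recognition particle. It fell by log2 -2.70 ± 0.14, with -2.48 on its second probe set.

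Of the 33297 probe sets, 614 passed in limma, 286 higher and 328 lower in the combined knockdown, and 5089 had an unadjusted p under 0.05. The called probe sets named 239 genes that rose and 254 that fell. Their median change was 2.27-fold, and 434 changed at least 2-fold. Further large rises were ACTBL2 (log2 3.55 ± 0.23), the integrin subunit ITGB3 (3.52 ± 0.29), osteoprotegerin (TNFRSF11B, 3.31 ± 0.30), ODAPH (3.26 ± 0.51), the thioredoxin-binding protein TXNIP (3.19 ± 0.28), the small GTPase RHOJ (3.10 ± 0.14), the hyaluronan and proteoglycan link protein HAPLN1 (3.02 ± 0.34) and the collagenase MMP13 (2.90 ± 0.37), with adjusted p between 0.0046 and 0.038. Further large falls were the adhesion receptor ADGRL4 (-2.64 ± 0.21), the acetylcholine receptor subunit CHRNA9 (-2.41 ± 0.22), endocan (ESM1, -2.24 ± 0.24), the mitochondrial ribosomal protein MRPL42 (-2.07 ± 0.21), the catalytic oligosaccharyltransferase subunit STT3B (-2.01 ± 0.16), the 14-3-3 protein YWHAH (-2.00 ± 0.15) and TMEM156 (-1.98 ± 0.25), with adjusted p between 0.013 and 0.025. Near the floor lay ACTBL2 and MMP13 in luciferase cells, at 3.29 and 3.64 log2 units, and ADGRL4 and CENPH in the combined knockdown, at 3.01 and 3.62.

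Camera called 10 of the 23 lists in the combined knockdown, 7 lower and 3 higher. The G2/M and mitosis list averaged -0.67 ± 0.12 (SD over the 2 arrays), with 54 of 55 genes lower. In it 11 genes fell over all genes tested and 44 when adjusted over the list alone (camera adjusted p = 4.3e-25, adjusted p = 0.32 with an estimated correlation). They included TMPO (log2 -1.79 ± 0.19), the anaphase activator CDC20 (-1.55 ± 0.16), anillin (ANLN, -1.17 ± 0.15) and CDCA2 (-1.09 ± 0.14). The G1/S and DNA replication list averaged -0.54 ± 0.07, with 40 of 41 genes lower, 3 fallen over all genes and 20 over the list alone (camera adjusted p = 1.9e-15, adjusted p = 0.41 with an estimated correlation). These 3 were the chromatin assembly factor subunit CHAF1B (-1.23 ± 0.13), the ribonucleotide reductase subunit RRM1 (-1.07 ± 0.13) and SLBP, which binds the stem-loop of histone mRNA (-0.84 ± 0.12). Replication-dependent H1, H2A, H2B and H4 genes averaged -0.44 ± 0.12, with H2AC15 fallen (-1.35 ± 0.20) among 43 measured, and 14 fallen and 1 risen when adjusted over the list alone (camera adjusted p = 1.9e-07, adjusted p = 0.44 with an estimated correlation). Of 22 H3 chaperones and chromatin assembly genes, CHAF1B and SSRP1 (-0.93 ± 0.12, -0.19 on a second probe set) fell, and 3 fell and 1 rose over the list alone (mean -0.23, camera adjusted p = 0.0039, adjusted p = 0.32 with an estimated correlation). Replication-dependent H3 genes were not called as a list (mean -0.25, camera adjusted p = 0.088), with H3C2 at -0.94 ± 0.21 and H3C1 at -0.59 ± 0.18. Among CDK inhibitors and G1 regulators, also not called as a list (mean -0.06, camera adjusted p = 0.52), cyclin A2 (CCNA2, -1.49 ± 0.14) and the retinoblastoma gene RB1 (-1.23 ± 0.15) fell and the CDK inhibitor CDKN1A (1.03 ± 0.16) rose.

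Extracellular matrix and osteoblast genes averaged log2 0.81 ± 0.10 above luciferase, with 31 of 34 genes higher. In that list 9 genes rose and 0 fell over all genes, and 17 rose over the list alone (camera adjusted p = 2.3e-13, adjusted p = 0.32 with an estimated correlation). Besides those above, COL11A1 (1.21 ± 0.13), MMP14 (1.47 ± 0.21), TIMP3 (2.19 ± 0.32), COL6A3 (0.90 ± 0.15) and COL5A1 (0.94 ± 0.16) rose. Of 30 p53 targets, PLK2 (1.70 ± 0.19), TP53INP1 (1.41 ± 0.16) and CDKN1A rose over all genes and 6 over the list alone (mean 0.36, camera adjusted p = 1.2e-04, adjusted p = 0.41 with an estimated correlation). Of 38 interferon-stimulated genes, IFIT3 (1.36 ± 0.23) and the chemokine CXCL10 (0.90 ± 0.15) rose over all genes and 4 over the list alone (mean 0.35, camera adjusted p = 1.2e-04, adjusted p = 0.50 with an estimated correlation). CXCL10 stayed near the floor of the arrays, at 3.35 ± 0.07 against 2.45 ± 0.22 log2 units. Another 3 lists were called lower, each with a small mean. They were heat shock genes (mean -0.22, camera adjusted p = 0.022), in which the mitochondrial chaperonin HSPE1 fell (-1.32 ± 0.12), cholesterol genes (-0.24, 0.010), with FDPS at -0.72 ± 0.15, and ribosomal protein genes (-0.11, 0.041), with RPL23 at -0.40 ± 0.18. Adjusted over the list alone, 5, 4 and 0 of their genes fell, and their adjusted p with an estimated correlation were 0.52, 0.50 and 0.41.

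The 13 lists not called in the combined knockdown had camera adjusted p between 0.068 and 1.00. Within them the hypoxia genes BNIP3 (-1.32 ± 0.14) fell and P4HA2 (1.07 ± 0.13) rose, the growth factor response gene SPRY2 (1.44 ± 0.13) rose and SPRED1 (-0.99 ± 0.13) fell, and PRKRA of the microRNA pathway (-0.93 ± 0.16) fell. The list of NF-kB and inflammatory genes had a mean of 0.22, oxidative phosphorylation -0.12, apoptosis regulators 0.02, unfolded protein response -0.02 and housekeeping genes -0.06, with 0 genes called in each. Among markers of other cell types, EPCAM, an epithelial adhesion molecule, rose by log2 2.25 ± 0.18 and by 2.73 on its second probe set, and was the 1 called gene of 17 epithelial markers (list mean 0.27, median 0.05, camera adjusted p = 0.068). Adjusted over the list alone, 4 of these markers rose and 0 fell, namely EPCAM, CLDN4 (0.70 ± 0.17), CDH1 (0.59 ± 0.14) and KRT14 (0.53 ± 0.15). Blood cell markers (mean 0.04) and neuroectodermal and germ line markers (mean 0.01, median -0.01, camera direction down) held 0 called genes. Mean and median also differed in sign for growth factor immediate early genes (0.01 and -0.08) and the microRNA pathway (-0.03 and 0.04). Fry called 6 lists, namely G1/S (adjusted p = 0.047) and, each at 0.023, G2/M and mitosis, extracellular matrix, H3 chaperones, replication-dependent H3 genes and the CDK inhibitors and G1 regulators.

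Leaving out either luciferase array or either combined knockdown array left 0 calls in limma for the combined knockdown (2852 to 3897 probe sets at an unadjusted p under 0.05), although each such fit rested on 1 array in that group. Without luciferase replicate 2, camera called 7 lists instead of 10, and the cholesterol, heat shock and ribosomal protein lists were lost, as they were without combined knockdown replicate 1, and the ribosomal protein list also without luciferase replicate 1.

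**Figure D2:**
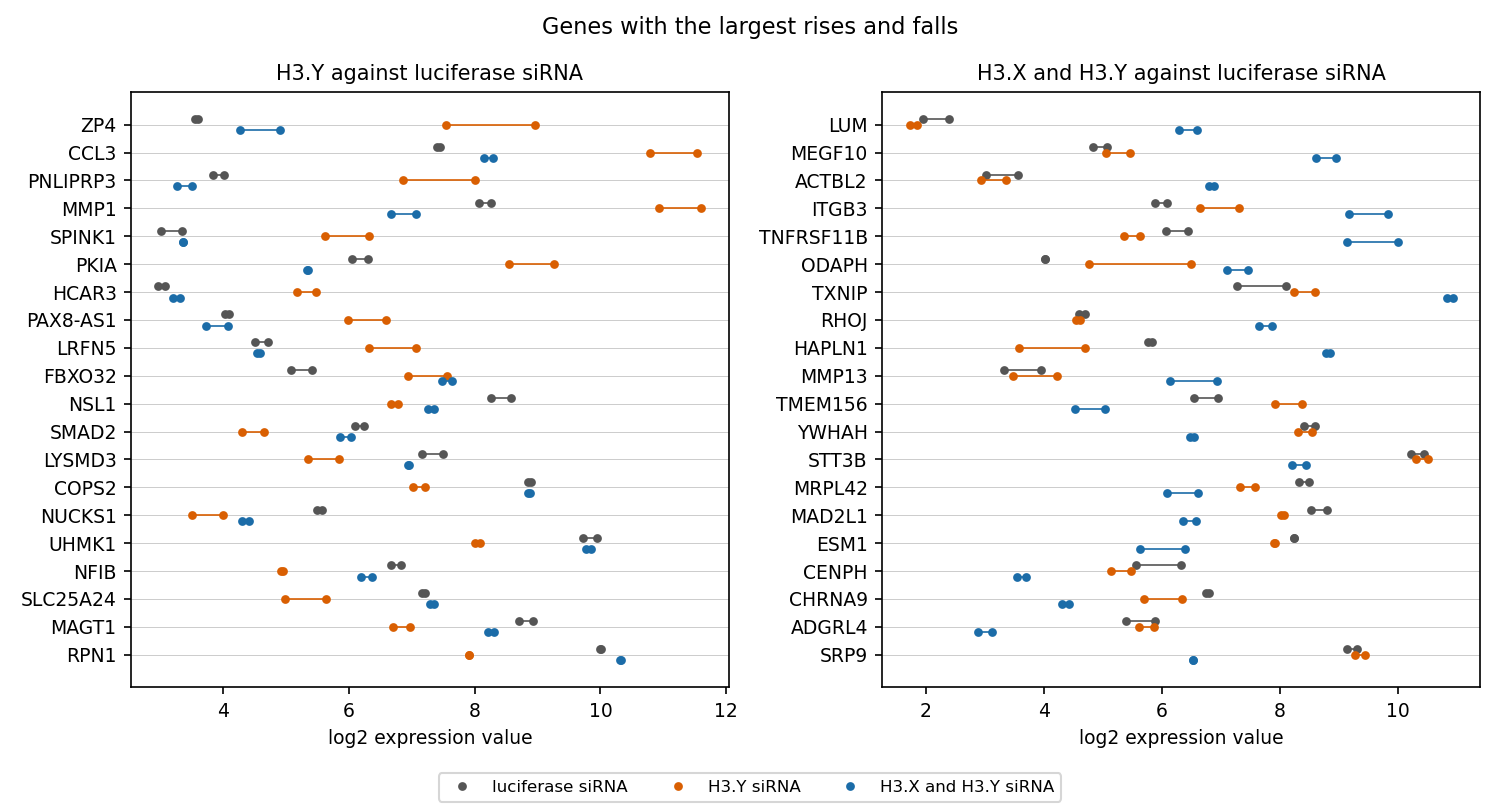
Log2 expression values on each array for the genes with the largest called rises and falls after H3.Y siRNA (left) and in the combined knockdown (right); points are arrays, coloured by group, and a line joins both arrays of a group. RPN1 lies at 7.91 after H3.Y siRNA against 10.00 in luciferase arrays, and SRP9 at 6.53 in the combined knockdown against 9.23 in luciferase arrays (group means).

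The knockdowns were then compared with each other, which tests directly whether their responses differed. HAPLN1 was higher in the combined knockdown than after H3.Y siRNA by log2 4.68 ± 0.34 (25.6-fold, n = 2 per group), LUM by 4.65 ± 0.20 and osteoprotegerin (TNFRSF11B) by 4.08 ± 0.30. EPCAM was higher by 3.95 ± 0.31 on the probe set that rose by 2.73 against luciferase in the combined knockdown. On the probe set that rose by 2.25 there, it was higher by 2.46. The lysyl oxidase LOXL4 was higher by 3.72 ± 0.21. Of the genes that H3.Y siRNA had raised, 4 were among the largest falls between the knockdowns, MMP1 by log2 -4.40 ± 0.25 (21.2-fold), PNLIPRP3 by -4.05 ± 0.35, ZP4 by -3.67 ± 0.45 and PKIA by -3.56 ± 0.24. Near the floor lay LUM and EPCAM after H3.Y siRNA, at 1.79 and 3.84 log2 units, and PNLIPRP3 in the combined knockdown, at 3.38. TMEM156 was lower by -3.38 ± 0.25, and all 10 of these genes had an adjusted p of 0.014 or less.

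Between the knockdowns 1554 probe sets passed in limma, 914 higher and 640 lower in the combined knockdown, naming 759 and 502 genes, with 6327 at an unadjusted p under 0.05. Camera called 4 of 23 lists. Interferon-stimulated genes were higher by a mean of log2 0.53, with 8 of 38 genes higher over all genes and 18 over the list alone, among them IFI44 (1.48 ± 0.20), OAS1 (1.24 ± 0.17), IFIT3 (1.57 ± 0.23) and HERC6 (0.98 ± 0.15) (camera adjusted p = 2.1e-06, adjusted p = 0.85 with an estimated correlation). Extracellular matrix genes were higher by a mean of 0.77, with 12 of 34 higher over all genes and 14 higher and 1 lower over the list alone, among them COL1A1 (2.10 ± 0.17) and COL11A1 (1.74 ± 0.13) (camera adjusted p = 1.3e-07, adjusted p = 0.85 with an estimated correlation). Epithelial markers were higher by a mean of 0.42 and a median of 0.11, with EPCAM, CLDN4 (1.51 ± 0.17) and KRT14 (0.86 ± 0.15) called over all genes and 6 over the list alone (camera adjusted p = 0.034, adjusted p = 0.85 with an estimated correlation). G2/M and mitosis genes were lower by a mean of -0.21, with 6 of 55 lower over all genes, among them GAS2L3 (-1.05 ± 0.16), CKS2 (-1.09 ± 0.20), CDCA2 (-0.84 ± 0.14) and CDCA3 (-0.82 ± 0.15), and 14 lower and 2 higher over the list alone (camera adjusted p = 0.0078, adjusted p = 0.94 with an estimated correlation). Fry called 0 lists here.

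In the 19 lists not called between the knockdowns, camera adjusted p lay between 0.23 and 0.94. Several held single genes that differed in opposite ways. Among them were the glycolysis and hypoxia genes P4HA2 (1.60 ± 0.13), CA12 (1.57 ± 0.20), ALDOC (1.00 ± 0.13) and ENO2 (-0.96 ± 0.13), the G1 regulators RBL2 (1.82 ± 0.20), E2F5 (-1.88 ± 0.30), SKP2 (0.82 ± 0.14) and CCNA2 (-0.81 ± 0.14), and the inflammatory genes CCL2 (1.43 ± 0.19) and PTGS2 (-1.73 ± 0.16). The cholesterol genes ACAT2 (1.18 ± 0.15) and HMGCS1 (1.17 ± 0.18) were higher, as were the p53 targets TP53INP1 (1.41 ± 0.16) and PLK2 (1.48 ± 0.19) and the housekeeping genes TFRC (1.55 ± 0.26) and GUSB (0.97 ± 0.14). The stress response genes NUPR1 (-1.23 ± 0.20), ATF4 (-0.73 ± 0.13, -0.27 on a second probe set) and EDEM1 (-0.92 ± 0.18) were lower, as were HSPE1 (-1.06 ± 0.12), the blood cell marker CD68 (-1.48 ± 0.25) and the neuronal marker SYP (-0.82 ± 0.16). Among apoptosis regulators BCL2A1 was lower (-1.96 ± 0.29), near the floor at 3.94 log2 units in the combined knockdown, and CASP6 higher (1.45 ± 0.30). The G1/S list had a mean of 0.02 with a camera direction down, NF-kB genes a mean of -0.09, a median of 0.11 and a camera direction up, and p53 targets a mean of 0.13 and a median of -0.01. Leaving out combined knockdown replicate 1 gave 12 calls between the knockdowns and replicate 2 gave 45, leaving out H3.Y replicate 1 gave 496, and leaving out either luciferase array, or fitting only the 4 arrays compared, gave 448. The G2/M list was not called between the knockdowns without H3.Y replicate 2 or without combined knockdown replicate 1, nor the epithelial list without H3.Y replicate 1.

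Both comparisons with luciferase shared their control arrays, so part of any likeness between them comes from those arrays, which were too few to split. Probe sets called in both comparisons included WDTC1, the growth factor VEGFC and FBXO32 (log2 2.01 after H3.Y siRNA and 2.32 in the combined knockdown), which rose in both. NUCKS1, FBXO28, SYT2, NSL1, TTL, TIMMDC1, RNF13, LRRC58, RAI14 and the chromatin-binding PSIP1 (-1.28 and -1.50) fell in both. In all 3 probe sets rose in both, against 0.24 for independent lists, and 13 fell in both, against 0.64, while unchanged groups simulated against the same controls gave 0. These simulated groups hold no effects and the independent lists no shared controls, so neither value measures shared effects. PPP1R14C, an inhibitor of protein phosphatase 1, was called in opposite directions, at log2 -1.43 ± 0.15 after H3.Y siRNA and 1.17 ± 0.15 in the combined knockdown. So were the annexin ANXA3 (-1.19 ± 0.14 and 0.88 ± 0.14) and the collagen COL6A3 (-1.41 ± 0.15 and 0.90 ± 0.15), which makes 3 probe sets against 0.83 for independent lists.

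Across all probe sets, which are not independent replicates, the log2 fold changes of both knockdowns had a covariance of 0.0398 against a simulated 0.0322 for unchanged groups with these controls, a difference of 0.0076, and against 0.0278 computed from the spread of the luciferase arrays alone, a difference of 0.0120. Their correlation was 0.308 against a simulated 0.50, and 62.0% had the same sign against a simulated 66.6%. Effects particular to 1 knockdown lower both values, so these do not show knockdowns less alike than unchanged groups. Without luciferase replicate 1 the covariance was 0.0812 and without replicate 2 it was 0.0539. Unchanged groups with 1 control array gave a simulated 0.0642. The differences from it, 0.0170 and -0.0103, had opposite signs, so a covariance beyond that of shared controls cannot be told. Of the 28 probe sets that rose after H3.Y siRNA, 23 differed between the knockdowns in the direct test, with median log2 changes of 2.04 after H3.Y siRNA and 0.28 in the combined knockdown. Of the 65 that fell, 49 differed, with medians of -1.46 and -0.38, and 47 had the same sign in the combined knockdown. Of the 286 that rose in the combined knockdown 220 differed, with medians of 1.24 there and 0.11 after H3.Y siRNA, and of the 328 that fell 209 differed, with medians of -1.15 and -0.24. Each set was chosen on arrays that the direct test uses again. In 50 simulations of equal effects, with spread independent between probe sets, at most 2 probe sets of such a set differed.

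**Figure D3:**
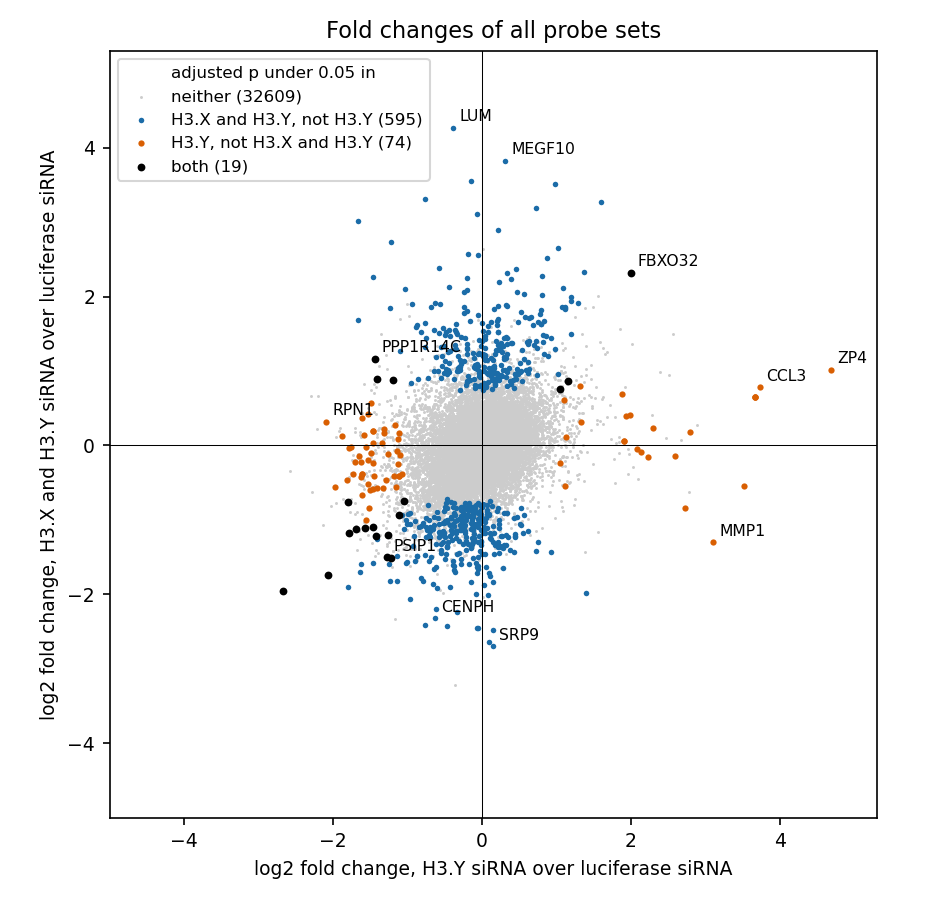
Log2 fold changes against luciferase siRNA of all 33297 probe sets, after H3.Y siRNA (horizontal axis) and in the combined knockdown (vertical axis); colours mark which comparison called the probe set, and both axes share the same control arrays. The 3 black points at upper left are PPP1R14C, ANXA3 and COL6A3, called in opposite directions.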

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

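The tests of the siRNA sequence, of the luciferase arrays, of epithelial cells and of a single probe set were chosen after the results were seen. The matched random lists and the simulation of equal effects were set before their results were seen. Called in opposite directions by the knockdowns, with a difference that itself passed in limma, PPP1R14C was higher in the combined knockdown than after H3.Y siRNA by log2 2.60, COL6A3 by 2.31 and ANXA3 by 2.07. Interferon-stimulated genes were called lower as a list by camera after H3.Y siRNA and higher in the combined knockdown (adjusted p = 0.69 and 0.50 with an estimated correlation), with a mean difference of log2 0.53 (camera adjusted p = 2.1e-06, adjusted p = 0.85 with an estimated correlation). The list lay at -0.22 and -0.14 on the H3.Y arrays, where luciferase replicate 1 itself lay at -0.12. The call after H3.Y siRNA was lost without luciferase replicate 2 (adjusted p = 0.56) and without H3.Y replicate 1 (0.15), in a range from 3.8e-04 to 0.69 over 16 alternatives.

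The G1/S and G2/M lists were called lower by camera in both knockdowns, and with an estimated correlation their adjusted p were 0.35 and 0.35 after H3.Y siRNA and 0.41 and 0.32 in the combined knockdown. A general fall of probe sets at their brightness was argued against by 10000 random lists matched on mean expression, of which 0 had a median as low for either the G1/S or the G2/M list in either knockdown. Luciferase arrays that happened to lie high would shift both knockdowns alike. The G2/M list was lower in the combined knockdown than after H3.Y siRNA by a mean of log2 -0.21. Its camera adjusted p was 0.0078, and 0.94 with an estimated correlation, a test that could hardly pass here. The G1/S list differed between the knockdowns by a mean of 0.02 (camera adjusted p = 0.88). Neither result tells where the luciferase arrays lie. With 2 control arrays, a high control cannot be told apart from an effect of the knockdowns. A smaller share of dividing cells after knockdown is a biological candidate explanation that was not tested.

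EPCAM was higher in the combined knockdown. Admixed epithelial cells would also bring other abundant epithelial transcripts, but the 16 other markers of the list had a median log2 change of 0.034 with an SD of 0.29 between them, below the bound of 1.13 set at 50% of the weaker EPCAM rise. Of these markers, CLDN4 (0.70), CDH1 (0.59) and KRT14 (0.53) rose when adjusted over the list alone, and CLDN4 and KRT14 were also higher than after H3.Y siRNA over all genes, so a smaller contribution of such cells is not excluded. A fault of a single probe set is argued against by the rise on both of the 2 EPCAM probe sets. Their sequences were not compared, so a fault that both share is not excluded. A change of EPCAM expression in the U2OS cells may remain as a hypothesis, and whether it follows from loss of H3.X was not tested.

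The probe sets called against luciferase were largely different for the knockdowns, although both target H3.Y. Those with the same sign in the other knockdown were 19 of 28 risen and 47 of 65 fallen after H3.Y siRNA. For the combined knockdown they were 169 of 286 risen and 251 of 328 fallen, with the control arrays shared. If both had the same effects, blurred by replicate spread, the direct comparison would call few probe sets. Simulations of equal effects drew the spread independently for each probe set, so they cannot exclude shifts that many probe sets share on an array. The 50 simulations gave at most 2 calls against the observed 1554. They do not cover the case of the same probe sets changed by different amounts. The count fell to 12 without combined knockdown replicate 1. Of the 65 probe sets that fell after H3.Y siRNA, 49 differed from the combined knockdown although 47 had the same sign there. This may come from transcripts hit by the sequence of one siRNA and not the other, or from loss of H3.X. It may also come from other differences between the groups, such as the degree of knockdown. These causes cannot be told apart, since siRNA and transcript sequences were not used here and the targets themselves were not measured.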

How the results depend on the processing

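All alternatives below were planned. No called result of a named gene or of a list changed direction under any alternative run for it. The sign of uncalled values changed in 8 of 1184 cases for named genes and in 40 of 736 for lists. The largest rises and falls were chosen with arrays that did not overlap, so leaving out 1 array could not reverse them. Settings that alter only the variance leave the fold change of a gene as it is. Calls were lost, however. With only the 4 arrays compared, 53 calls of named genes were lost, and with an estimated correlation 23 list calls. Calls for H3.Y siRNA, the combined knockdown and the comparison between them (93, 614 and 1554) became 413, 1237 and 2436 without the dimmest 40%, and 823, 1479 and 2629 with 1 probe set per named gene. A variance trend gave 205 and 960 for the comparisons with luciferase, and a trend with robust variances 209 and 924. Array weights gave 35 and 1346. An adjusted p under 0.1 gave 464, 1340 and 2887. With only the 4 arrays compared, H3.Y siRNA had 0 calls and the knockdowns 448 between them. Leaving out each array in turn gave 0 to 629, 0 to 644 and 12 to 1641 calls, with 1 residual degree of freedom fewer and the lone array assumed to vary like the other groups. Other causes were not tested. List calls (9, 10 and 4) became 0, 0 and 0 with an estimated correlation and 2, 6 and 0 with fry. Quantile normalization again gave 7, 8 and 4. Without each array they ranged from 4 to 10, 7 to 11 and 3 to 4. The covariance of the knockdowns (0.0398) was 0.0319 with 1 probe set per named gene, and ranged from 0.0345 to 0.0812 without each array. Quantile normalization again (92, 641 and 1626) and median centring (110, 591 and 1528) moved no count of calls by over 1.5 times. The minimum fold of 1.5 removed no call. ZP4 was the 1 named gene whose fold moved by over 1.5 times, with log2 3.98 and 5.39 instead of 4.68 after H3.Y siRNA, and -2.96 and -4.37 instead of -3.67 between the knockdowns, without H3.Y replicate 1 and replicate 2. No background signal came with the values, so levels near the floor, such as LUM in luciferase cells, were not set against background. The siRNA targets gave no value under any setting, since no probe set was named for them.

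Replicate numbers were shared between groups, but each comparison had 2 pairs and no label says that a number marks a shared day, so the numbers were not taken as pairs. With the replicate block, limma called 68, 750 and 1778 probe sets, of which 53, 555 and 1436 were also called without it. Among named genes 12 calls were lost, 7 for H3.Y siRNA, 3 for the combined knockdown and 2 between the knockdowns. The 2 calls gained were for H3.Y siRNA. Replicate differences correlated across probe sets by 0.220 between luciferase and H3.Y, 0.280 between luciferase and the combined knockdown and 0.122 between the knockdowns, a hint from the data, not the design.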

Other observations

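The gene groups in this part were chosen after the data were seen, so their counts describe these arrays and are not independent evidence. Of 25 measured genes that respond to FOXO transcription factors, 6 rose in the combined knockdown over all genes in limma, namely TXNIP (log2 3.19 ± 0.28), FBXO32 (2.32 ± 0.24), SESN3 (1.62 ± 0.17), DEPP1 (1.52 ± 0.14), TP53INP1 (1.41 ± 0.16) and PIK3IP1 (1.39 ± 0.21). The list had a mean of 0.80, with 25 genes positive and 0 negative, and with members such as IRS2 (0.01 ± 0.17) and SOD2 (0.02 ± 0.18) near 0. Its mean after H3.Y siRNA was 0.25, with 16 genes positive, 9 negative and FBXO32 the 1 gene called. In the direct test of the knockdowns 7 genes were higher in the combined knockdown, among them RBL2 (1.82 ± 0.20) and SESN3 (2.50 ± 0.17). After H3.Y siRNA itself RBL2 lay at -1.17 ± 0.20 and SESN3 at -0.88 ± 0.17 against luciferase, neither called. Among 24 genes of a TGF-beta response list, which also holds TGFB1, TGFB3 and TGFBR1, 9 were called higher in the combined knockdown and 0 lower. INHBA (2.66 ± 0.24), THBS1 (2.57 ± 0.27), SNAI2 (2.23 ± 0.32), TGFB2 (2.05 ± 0.34) and PMEPA1 (1.91 ± 0.18) were the highest. Of the 24 genes 17 were positive and 7 negative, the lowest being ID3 (-1.12 ± 0.25) and ID1 (-0.43 ± 0.22). The list mean was 0.69 and the median 0.37. After H3.Y siRNA the list mean was 0.05 with 0 called by limma. That comparison had 4618 probe sets at an unadjusted p under 0.05. The FOXO list shares 8 genes and the TGF-beta list 4 with lists fixed before, and the kinetochore and spindle checkpoint list below shares 4.

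Kinetochore and spindle checkpoint genes held 6 falls among 24 in the combined knockdown, with CENPH (log2 -2.32 ± 0.27), MAD2L1 (-2.19 ± 0.16) and KNL1 (-1.53 ± 0.14) the lowest, and 2 falls after H3.Y siRNA, NSL1 (-1.70 ± 0.15) and ZWINT (-1.07 ± 0.13). KNL1, MAD2L1 and CENPH were lower in the combined knockdown than after H3.Y siRNA in the direct test, by -1.04 ± 0.14, -1.57 ± 0.16 and -1.69 ± 0.27, and ZWINT was higher by 0.70 ± 0.13.

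Single subunits of the machinery that imports and glycosylates proteins differed between the knockdowns. RPN1 (-2.09 ± 0.12) and MAGT1 (-1.97 ± 0.16 on the brighter of its 2 probe sets, 0.03 on the other) fell after H3.Y siRNA. Both were higher in the combined knockdown than after H3.Y siRNA, by 2.41 ± 0.12 and 1.42 ± 0.16. MAGT1 was at -0.55 ± 0.16 in the combined knockdown, short of the threshold. STT3B (-2.01 ± 0.16) and SRP9 (-2.70 ± 0.14) fell in the combined knockdown and differed from H3.Y siRNA by -2.09 ± 0.16 and -2.84 ± 0.14. The other measured subunits of the oligosaccharyltransferase and the signal recognition particle did not pass against luciferase, for example RPN2 (-0.17 ± 0.17 and 0.29 ± 0.17 in the respective knockdowns), STT3A (-0.46 ± 0.13 and 0.12 ± 0.13) and SRP14 (0.21 ± 0.15 and 0.03 ± 0.15).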
